A study of Mus musculus with 12 samples.

How the data were processed

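RNA was measured in 12 libraries of the mouse Leydig cell line mLTC-1, 6 treated with vehicle and 6 with 100 µM MSNBA for 24 h. The authors deposited a single table of raw counts per gene symbol, with a column for each library and no normalization. The submitters' processing notes name BWA 0.7.4.4 and the mm10 assembly. The table's name points to uniquely aligned reads on RefSeq genes counted by molecular identifier, which the labels do not spell out, and the counting program, annotation release and strand are not given in the sources used here. Reads of overlapping genes on opposite strands can therefore not be told apart. Values were whole numbers, with totals from 59113 to 657251. The columns stand in the order of libraries 1, 4, 7, 10, 2, 5, 11, 8, 3, 6, 9 and 12, which reads as 3 sets of 4, whereas the labels give 2 groups of 6: libraries 1, 2, 4, 5, 7 and 10 as controls 1 to 6, and 3, 6, 8, 9, 11 and 12 as MSNBA 1 to 6. Groups were taken from the labels and the order was used in no test, so that every comparison rests on the labels being right. Gene positions were taken from RefSeq, in which 2613 of the 2614 tested symbols were matched.

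Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Genes were filtered by filterByExpr with the groups, scaled by TMM factors and tested by the edgeR robust quasi-likelihood F test with an intercept and treatment. P-values were two-sided and adjusted by Benjamini-Hochberg over the 2614 tested genes, with a threshold of 0.05. The standard error of a log2 fold change was its size over the square root of F. The common biological coefficient of variation was 0.143, and the median log2 fold change of all tested genes was -0.0082. Lists with at least 5 tested genes were tested by limma camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 19 lists. Of 32 lists fixed before the data were examined, 13 had too few tested genes. Pooled counts carry exact Poisson intervals at 95%, and a floor is 3 counts over a group. Normalized CPM of single genes are over the counts of the tested genes, with TMM factors. Pooled CPM, summed list CPM and floors are over full library totals without those factors, so their scale differs from that of single genes.

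Genes named were fixed by rule before the data were examined. The rule takes 13 genes of the study's question, then up to 8 rises and 8 falls among genes past the threshold with a mean of at least 10 counts and no overlap between groups, then members past the threshold of each list. Its last parts named no gene, and genes outside it were named after their values were seen. A further list of 26 liver genes was written after the data were examined.

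The test was tried on simulated data with the same depths in 10 runs with 200 changed genes each, where 4.23% of calls were false. A shifted list, oxidative phosphorylation with 69 tested genes, was found in 10 of 10 runs, with 0 other lists called. Its shift was larger than the largest list median in the data, 0.19 on the log2 scale, and most lists had fewer tested genes. The runs therefore give no recovery rate for the lists reported. Genes were drawn independently of each other in these runs. In the data, the 4 lists past the threshold had estimated correlations from 0.098 to 0.23. The runs therefore give no rate of false list calls for the data. Replicate numbers were tested for pairing: the correlation of same-number residuals over 1077 genes passed 0.1 in 3 of 6 pairs. It ran from -0.27 to 0.57, and the reported test used no block. Controls 2, 3 and 6 were most similar to MSNBA 6, 2 and 1. A check of equal numbers cannot show a block that follows another order, and no such block was modelled.

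Alternatives were DESeq2, limma-voom, library size alone, RLE and upper-quartile factors, no filter, a stricter filter of 20 counts in 6 libraries, thinning to equal depth, a replicate block, 1 surrogate variable, a minimum absolute log2 fold change of 1, an estimated correlation, fry, and each library left out in turn. Depth as a covariate and leaving out controls 2 and 4 were added after the data were seen. The fit was repeated over 100 splits of the libraries, the real one included. No library was left out of the reported test. The values of 1 member of the cholesterol synthesis list are not reported here.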

Results

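The series profiled polyA RNA from mLTC-1, an immortalized mouse Leydig cell line, by sequencing of tagmented libraries. Leydig cells are the androgen-producing cells of the testis. Cells received 100 µM MSNBA, a small molecule that the series describes as an inhibitor of the fructose transporter Glut5, or the DMSO vehicle alone, for 24 h before RNA was taken. There were 6 control and 6 MSNBA libraries by the labels, which no independent source here could check. The table held whole-number counts for 26214 gene symbols, of which 19576 had at least 1 count. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

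Total counts in control replicates 1 to 6 were 234225, 77030, 83983, 79770, 59113 and 145516. In MSNBA replicates 1 to 6 they were 657251, 150623, 342488, 94179, 181614 and 172131. MSNBA libraries were 2.14-fold deeper by geometric mean (exact two-sided permutation test, p = 0.0606). After a filter on low counts, 2614 genes holding 79.2% of all counts were tested. On simulated data with these depths, the test recovered 26.6% of genes changed by 0.5 on the log2 scale, 87.8% of those changed by 1 and 99.8% of those changed by 2. Each run held 200 changed genes, drawn independently of each other. Where fewer genes change, the adjusted threshold is harder to reach. These rates are therefore no estimate for the data, in which 2 genes passed.

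The single comparison, MSNBA against control, asks how the Leydig cell transcriptome, and its steroid and metabolic genes in particular, differs on exposure to a compound described as a Glut5 inhibitor. Glut5 activity was not measured in these data. Nrg1, which encodes a growth factor that binds ErbB receptors, fell from 322 ± 105 to 168 ± 54.5 normalized CPM (counts scaled to a common library size, mean ± SD, n = 6 per group). Actn4, which encodes an actin-crosslinking protein, fell from 506 ± 116 to 299 ± 66.2 CPM (SD, n = 6 per group). Among 19 gene lists tested, those for ribosomal proteins, the integrated stress response, fatty acid synthesis and cholesterol synthesis rose relative to the other genes at a preset correlation, and each had an adjusted p = 0.561 with an estimated correlation. No steroidogenic gene passed the threshold.

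By edgeR, 0 genes were higher and 2 were lower at an adjusted p of 0.05, while 109 were higher and 125 lower at an unadjusted p under 0.05, where chance gives 130.7 in all. The log2 fold change of Nrg1 was -1.04 (SE 0.21, adjusted p = 0.0295) and that of Actn4 was -0.79 (SE 0.17, adjusted p = 0.0409). For each of these genes, 5 of 6 MSNBA libraries lay below all controls. Both were named after their values were seen, since their groups overlap and the rule for naming genes takes only genes without overlap. Nrg1 lies on chromosome 8 from 31807452 to 32891609 and Actn4 on chromosome 7 from 28893248 to 28962351 of the mm10 assembly. DESeq2, which tested 19572 genes, called 0, with 394 at an unadjusted p under 0.05 where chance gives 978.6, and 177 of these were among the 2614 genes tested by edgeR. Limma-voom, on those 2614 genes, called 0, with 259 at an unadjusted p under 0.05. With library depth in the model, the log2 fold changes were -0.70 (SE 0.23) for Nrg1 and -0.60 (SE 0.19) for Actn4, and neither passed (adjusted p = 0.388). The counts were 8 higher and 7 lower without the low-count filter and 10 higher and 12 lower with 1 surrogate variable. That variable weighed mainly on control 2 (0.83, against -0.31 to 0.21 in the other libraries). Without the low-count filter the median log2 fold change of the 2614 genes was 0.14, against -0.0082 in the reported test. The count of lower genes was 0 without control 4, 5 or 6 and without MSNBA 1, 2, 3, 5 or 6, it was 1 without control 3, 5 without control 1 and 4 without MSNBA 4.

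**Figure D1:**
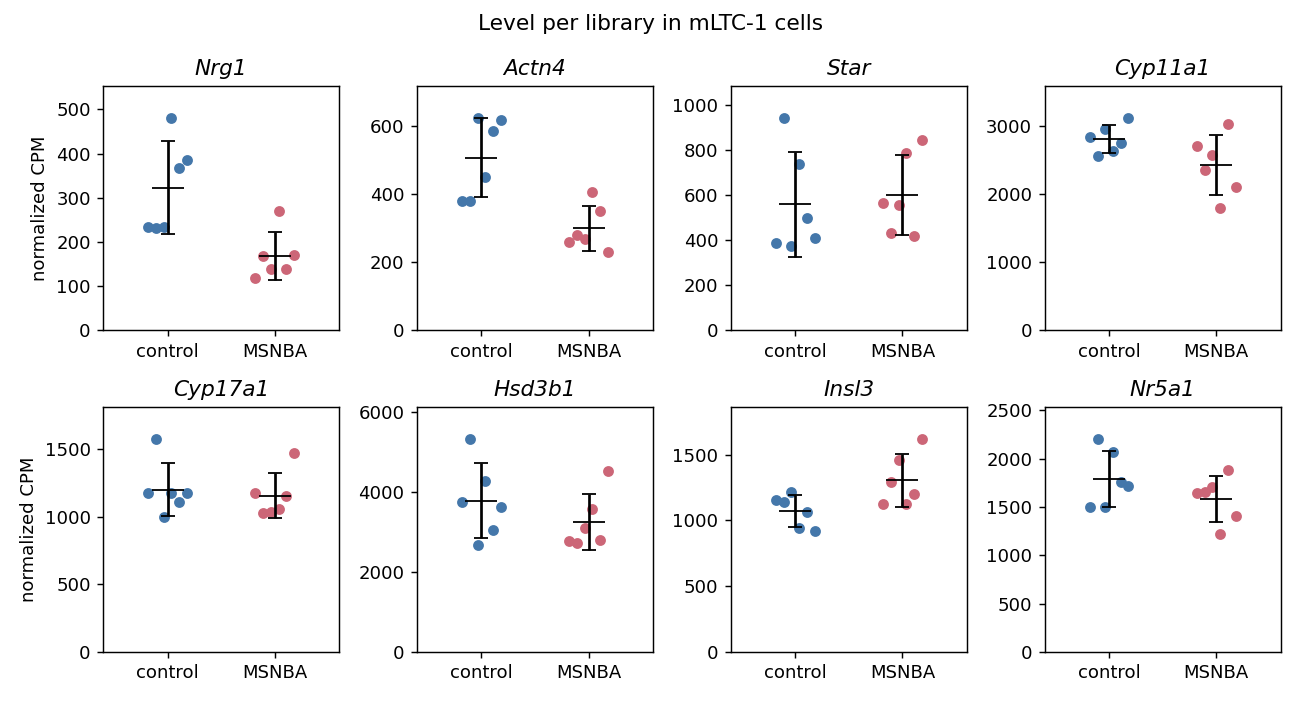
Normalized CPM (vertical axes, from 0) of 8 genes in the 6 control and 6 MSNBA libraries. Points are libraries, and bars give the mean ± SD. In the panels of Nrg1 and Actn4, 5 of 6 MSNBA libraries lie below all controls, and the groups overlap in all 8 panels.

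Among genes of the study's question, Star, which carries cholesterol into mitochondria, measured 558 ± 232 CPM in controls and 599 ± 178 CPM in MSNBA (SD, n = 6 per group). Its log2 fold change was 0.14 (SE 0.25, adjusted p = 0.911), and the 95% interval ran from 0.756-fold to 1.61-fold. With 1 library left out the log2 value ran from 0.011 (without control 1) to 0.34 (without control 2). Cyp11a1, which cleaves the cholesterol side chain, measured 2817 ± 208 and 2433 ± 441 CPM, a log2 fold change of -0.21 (SE 0.11, adjusted p = 0.566). For Cyp17a1, the next cytochrome of the androgen pathway, the value was -0.05 (SE 0.12), and its sign turned without the low-count filter, after thinning to equal depth, with a surrogate variable, without controls 2 and 4 and without control 2 alone (0.029). Hsd3b1 had a value of -0.23 (SE 0.16) and Lhcgr, the luteinizing hormone receptor, 0.32 (SE 0.26). Nr5a1, a regulator of steroidogenic genes, had -0.15 (SE 0.11), with a sign that turned without the low-count filter and a value of -0.088 without control 2. Without that filter the median of all genes of the reported test moved from -0.0082 to 0.14. The turned signs of Cyp17a1 and Nr5a1 in that setting are therefore not particular to them. Insl3, a peptide hormone of Leydig cells, measured 1073 ± 120 and 1304 ± 199 CPM, a log2 fold change of 0.28 (SE 0.12, unadjusted p = 0.0187, adjusted p = 0.401). The steroidogenesis list had 14 tested genes, a median log2 fold change of -0.07 and an adjusted p of 0.514. With 1 library left out the median ran from -0.11 (without MSNBA 5) to -0.020 (without control 1), the value of Hsd3b1 from -0.34 to -0.11 and that of Lhcgr from 0.12 to 0.49, and none of them passed.

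Slc2a5, which encodes Glut5 (chromosome 4, 150119344 to 150144168), had 1 count over the 6 control libraries and 1 over the 6 MSNBA libraries, so that its difference was not detectable at this depth. The ketohexokinase gene Khk, the first step of fructose use, measured 136 ± 25.9 and 118 ± 33.2 CPM, with a log2 fold change of -0.34 (SE 0.24, adjusted p = 0.676). Slc2a1, a glucose transporter gene, measured 99.5 ± 52.3 and 149 ± 18.7 CPM (log2 fold change 0.53, SE 0.25, adjusted p = 0.536). With 1 library left out, Khk ran from -0.47 (without MSNBA 5) to -0.16 (without MSNBA 1) and Slc2a1 from 0.32 (without control 6) to 0.85 (without control 1), and neither passed. Hsd17b3, whose enzyme makes testosterone, had 0 counts in all 12 libraries, and a floor of 3 counts is 4.41 CPM over the control group and 1.88 CPM over the MSNBA group. Hsd3b6 had 6 and 30 counts and Scarb1 had 23 and 52 counts in the control and MSNBA groups, too few to be tested. Intervals and floors cover counting error only.

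Ribosomal protein genes rose as a list: the median log2 fold change of the 74 tested members was 0.16 (adjusted p = 4.66e-06, and adjusted p = 0.561 with an estimated correlation), with 65 values above 0 and 9 below. Over all genes 0 members passed, and adjusted over the list alone 0 passed, although 17 were higher at an unadjusted p under 0.05 by edgeR. Rps23 had a log2 fold change of 0.42 (SE 0.13) and Rpl5 one of 0.45 (SE 0.14). The list's score, its mean log2 CPM centered over the libraries, was -0.072 in MSNBA 1, within the control range of -0.11 to -0.029. By fry, which asks whether the members move one way on balance and does not compare them with other genes, the adjusted p was 0.0344. Many ribosomal protein genes have near-identical processed pseudogenes, so their counts depend on how shared reads were assigned.

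Integrated stress response genes, which cells switch on through the factor Atf4, rose as a list of 22 tested members with a median log2 fold change of 0.19 (adjusted p = 0.0114, and adjusted p = 0.561 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 2 passed, Atf4 at 0.60 (SE 0.16) and the asparagine synthetase gene Asns at 0.72 (SE 0.23). At an unadjusted p under 0.05, 3 members were higher by edgeR, the third being Trib3 at 0.84 (SE 0.36). Over full library totals without TMM factors, the summed level of the list was 9477 CPM in control 2 and 8136 CPM in control 4. It ran from 5323 to 5773 CPM in the other controls and from 6618 to 9272 CPM in MSNBA. With controls 2 and 4 left out, a choice made from these values and so no independent evidence, edgeR called 4 genes higher and 3 lower, and the list's median was 0.32. The median was 0.13 without control 1 and 0.12 without control 3, and the list did not pass without control 1, 3, 5 or 6 or MSNBA 4 or 6 (adjusted p from 0.0841 to 0.358).

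**Figure D2:**
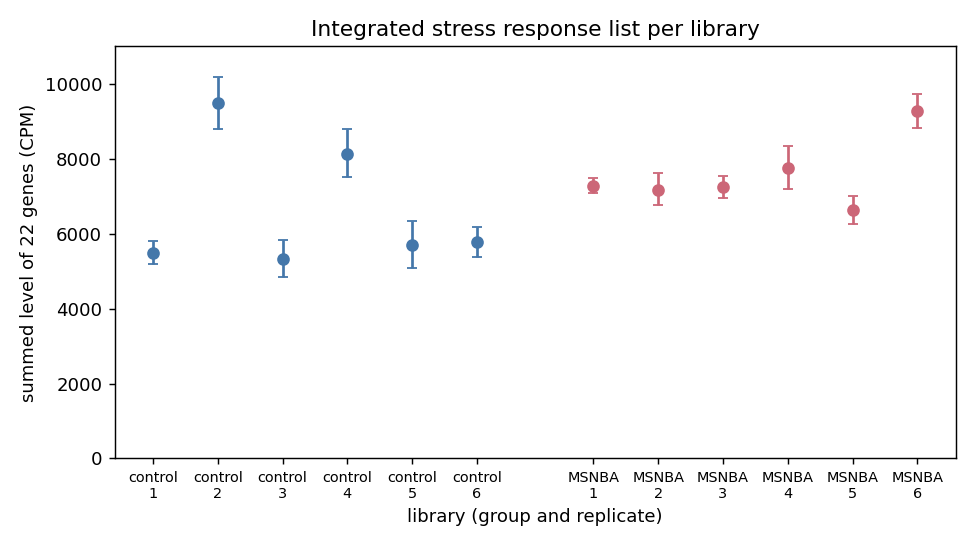
Summed level of the 22 tested integrated stress response genes (vertical axis, CPM of full library totals) in each library by group and replicate. Bars are 95% counting intervals. Controls 2 and 4 sit at 9477 and 8136 CPM, and the other controls between 5323 and 5773 CPM.

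Fatty acid synthesis genes rose as a list of 15 tested members with a median log2 fold change of 0.12 (adjusted p = 0.0114, and adjusted p = 0.561 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 1 passed, the desaturase gene Scd2 at 0.37 (SE 0.12), beside Scd1 at 0.40 (SE 0.17). At an unadjusted p under 0.05, 2 members were higher by edgeR. Cholesterol synthesis genes rose as a list of 22 tested members with a median of 0.17 (adjusted p = 0.0443, and adjusted p = 0.561 with an estimated correlation), but 14 values were above 0 and 8 below. Over all genes and adjusted over the list alone, 0 members passed, with 5 higher and 2 lower at an unadjusted p under 0.05 by edgeR. The sterol enzyme gene Sqle had a log2 fold change of 0.43 (SE 0.15) and Hsd17b7 one of -0.65 (SE 0.22). The cholesterol synthesis median was 0.0995 without MSNBA 4 and 0.11 without MSNBA 6, and the list did not pass without control 1, 2, 3 or 6 or MSNBA 4 or 6 (adjusted p from 0.0891 to 0.327). By the same list test it also missed the threshold with the stricter filter (adjusted p = 0.133), the replicate block (0.0526) and without controls 2 and 4 (0.0652). Fatty acid synthesis did not pass with library depth in the model (median 0.080, adjusted p = 0.129), nor without control 5 or MSNBA 4 or 6 (adjusted p from 0.0631 to 0.144). In that depth model, chosen after the data were seen, cholesterol synthesis passed at the preset correlation (median 0.26, adjusted p = 0.0011 by camera). The stress response list also passed there (median 0.26, adjusted p = 1.5e-04). DESeq2 and limma-voom called 0 genes in any list. The 4 list calls became 2 without control 1, 3, 5 or 6 and 1 without MSNBA 4 or MSNBA 6, where ribosomal proteins alone passed.

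**Figure D3:**
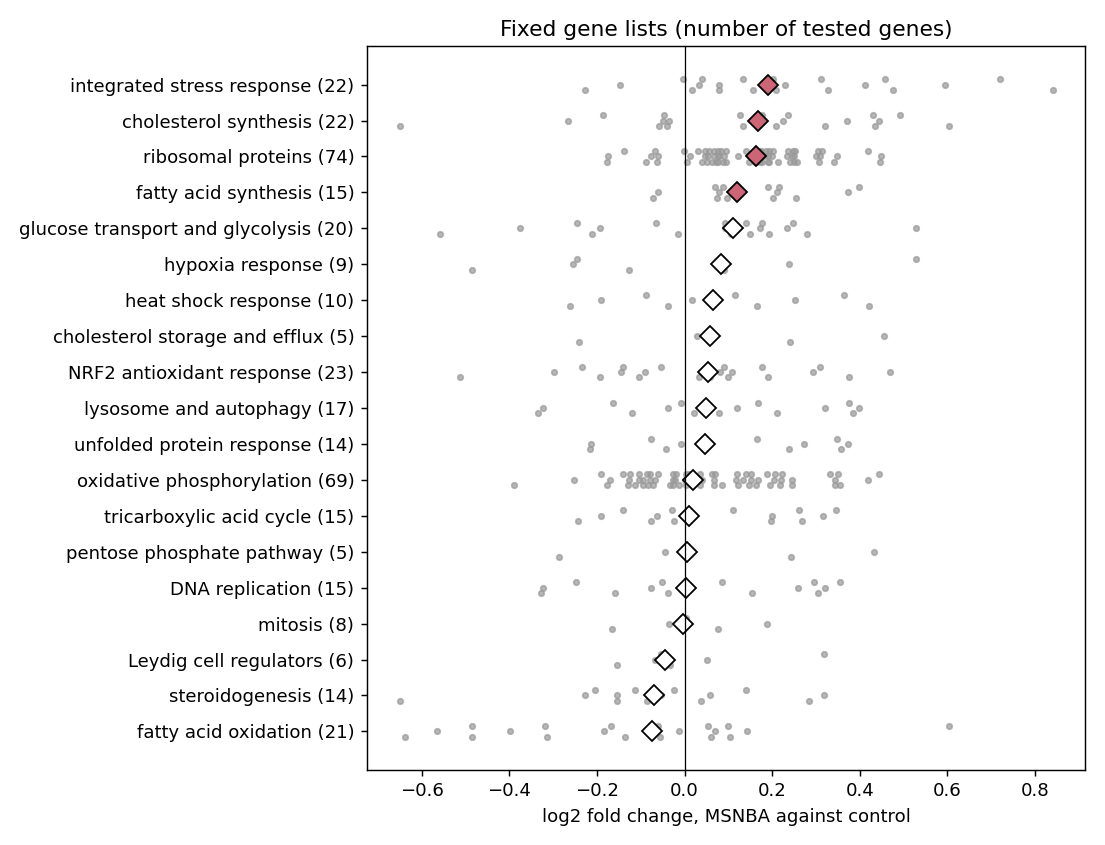
Log2 fold change, MSNBA against control (horizontal axis), of the tested members of 19 gene lists fixed before the data were examined. Grey points are genes and diamonds are list medians, filled for the 4 lists with an adjusted p under 0.05 at the preset correlation.

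In the other 15 lists 0 members passed over all genes by edgeR, DESeq2 or limma-voom, and the list test gave adjusted p-values from 0.401 to 0.986. The median log2 fold change was 0.11 for glucose transport and glycolysis, -0.075 for fatty acid oxidation, 0.020 for oxidative phosphorylation, 0.0095 for the tricarboxylic acid cycle and 0.0051 for the pentose phosphate pathway. It was 0.05 for the NRF2 antioxidant response, 0.05 for the unfolded protein response, 0.07 for the heat shock response, 0.05 for lysosome and autophagy and 0.06 for cholesterol storage and efflux. With 1 library left out, the medians of 6 of these lists moved in size but kept their sign. They ran from 0.043 to 0.13 for glycolysis, -0.13 to -0.062 for fatty acid oxidation and 0.016 to 0.066 for oxidative phosphorylation. For heat shock they ran from 0.026 to 0.10, for lysosome and autophagy from 0.033 to 0.11 and for the NRF2 response from 0.036 to 0.081. None of the 6 lists passed in those runs. The sign turned in some runs for the tricarboxylic acid cycle (-0.035 to 0.12) and the pentose phosphate pathway (-0.083 to 0.12). It also turned for the unfolded protein response (-0.0069 to 0.12) and cholesterol storage and efflux (-0.0043 to 0.18). Adjusted over the list alone, Hadh and Pfkl and Gpx1 were lower and Hspa5, Npc2 and Hspa9 higher in their lists. Median, mean and test differed in sign for hypoxia response (median 0.084, mean -0.010), Leydig cell regulators (median -0.044, mean 0.0099) and mitosis (median -0.0041, mean 0.0067), and the DNA replication median was 0.0030.

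Another 13 lists had fewer than 5 tested genes. Pooled over a group's libraries, macrophage markers measured 33.8 CPM in controls and 20.6 CPM in MSNBA (23 and 33 counts), endothelial markers 17.7 and 13.1 CPM (12 and 21 counts), and fibroblast and peritubular markers 97.1 and 68.2 CPM. Germ cell markers measured 184 and 165 CPM and adrenal cortex markers 416 and 414 CPM. Sertoli cell markers measured 2807 and 2792 CPM, with Ctsl, a lysosomal protease gene, as the tested member. Pooled levels were 302 and 249 CPM for fructose and polyol metabolism, 1673 and 1716 CPM for the aryl hydrocarbon receptor response, 653 and 631 CPM for the p53 response and 416 and 390 CPM for immediate early and cAMP response genes. They were 658 and 766 CPM for interferon and inflammation and 525 and 427 CPM for YAP and cytoskeleton genes. These differences were not tested. The list of mitochondrially encoded genes was fixed as the symbols starting with mt-, and the table held 0 of them.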

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

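The counting test of depth for the stress list, the liver slope without Apoc1 and the match on length alone were chosen after the results they bear on were seen.

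For the 2 genes past the threshold, 5 of 100 splits of the libraries into groups of 6, the real one included, gave as many genes, and the highest other split gave 19. For the 4 lists, 6 of 100 splits gave as many, and the highest other count was 4. Chance is excluded for neither count. The median of the other splits was 0 genes. The split with 19 genes set controls 1, 2 and 6 with MSNBA 1, 3 and 6 against the rest. Those 6 libraries hold the first and last columns of each of the 3 sets of 4 in the column order. For each control, the MSNBA library with the most similar residuals lay on the same side of this split. Both matches were seen afterwards in these same data, and whether they mark a batch was not tested.

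Of 60 groups of 6 libraries tested for a lone library, 8 held one, where chance gives 3. Cyp17a1 measured 1572 CPM in control 2, and the next control had 1174 CPM. Cyp17a1 also measured 1469 CPM in MSNBA 6. The steroidogenesis list had its highest control score, 0.14 on the log2 scale, in control 2, and the stress response list its highest MSNBA score, 0.42, in MSNBA 6. The hypoxia list was lowest in control 4, at -0.23, and the tricarboxylic acid cycle list was lowest in control 3, at -0.31. Ribosomal proteins were lowest among MSNBA libraries in MSNBA 1, at -0.072. Slc2a1 was highest among them in MSNBA 2, at 186 CPM.

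Integrated stress response genes were high in controls 2 and 4, at 9477 and 8136 CPM. Low depth is argued against: the counting intervals of both libraries lay 1196 CPM or more above those of the other controls with under 100000 counts. A wrong label stays open, also because the column order reads as 3 sets of 4, with controls 2 and 4 in the set of MSNBA 3 and 5. On 100 genes outside the stress list, where 0 stands for the other controls and 1 for MSNBA, control 2 scored 0.653 and control 4 0.471 (mean 0.562), on either side of the lowest left-out MSNBA library at 0.616, but left-out controls reached 0.71, so the score could not separate the groups. No biological explanation was tested, since the labels give no difference among controls.

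Ribosomal protein genes were higher in MSNBA as a list at the preset correlation, with an adjusted p = 0.561 with an estimated correlation. With log2 depth in the model their median log2 fold change was 0.20, against 0.16 without it, which argues against the depth difference as the whole cause. MSNBA 1, the deepest library, had a list score of -0.072, within the control range of -0.11 to -0.029. The other MSNBA libraries scored 0.051 to 0.12. The depth term may lean on MSNBA 1, and it was not refitted without that library. Without MSNBA 1 and with no depth term the median was 0.19. Other genes matched on transcript length and level had a median of 0.034 over 100 draws, and 100 of the draws lay below 50% of the list's median, which argues against length. Genes matched on length alone gave 0.025. Treatment and shared reads of pseudogenes stay open, the latter untested.

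Liver genes were noticed because Alb had 8 to 22 counts in each library, with a slope on depth of 0.222 (95% interval -0.0562 to 0.50), the lowest of all tested genes. Reads from another library or tissue stay open as a candidate explanation, which the slopes cannot decide. The summed counts of the other 25 liver genes rose with depth with a slope of 0.873 (95% interval 0.753 to 0.994). A slope of 1 is proportional and one of 0 a constant count. The interval lies under 1, the bound set beforehand for such reads, but above that of Alb. As a sum, these genes did not share the near-constant count of Alb. Apoc1 holds 77.4% of the summed counts, and the slope without it was 0.792 (0.637 to 0.947). Against liver tissue itself, Ttr had 0 counts and Apoa1 had 9 beside 151 for Alb, and 8.99% of all tested genes also had an interval under 1. For a treatment difference the log2 group effect with depth in the model was 0.084; the bound set beforehand, a value of 0 or more, is met, but the interval from -0.28 to 0.45 spans 0, as does that of Alb alone (-0.40, from -1.06 to 0.26), so it cannot be told apart.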

How the results depend on the processing

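Depth as a covariate and leaving out controls 2 and 4 were chosen after the data were seen, the latter from stress gene values.

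The 2 lower genes became 0 by DESeq2, limma-voom, thinning to equal depth and the depth covariate, and 1 with the stricter filter or a minimum absolute log2 fold change of 1. With depth in the model the log2 fold change of Nrg1 moved from -1.04 (SE 0.21) to -0.70 (SE 0.23) and that of Actn4 from -0.79 (SE 0.17) to -0.60 (SE 0.19) and both calls ended (adjusted p = 0.388), with smaller folds and larger errors whose shares in this were not told apart. Calls were 8 higher and 7 lower without the low-count filter, where 1 of the 2 genes was still called, 10 and 12 with 1 surrogate variable, where both were, 4 and 3 without controls 2 and 4, and 0 and 3 with a replicate block, where Alb was the added gene. The surrogate variable was 0.83 in control 2 and ran from -0.31 to 0.21 in the other libraries, so it weighed mainly on control 2. The calls without the low-count filter came with a shift in the median log2 fold change of the genes of the reported test, from -0.0082 to 0.14. The cause of the changes in the calls was not tested. The 4 lists became 0 with an estimated correlation. Fry, which tests a list against no change and not against other genes, called 1. Cholesterol synthesis missed the threshold with the stricter filter (adjusted p = 0.133), the replicate block (0.0526) and without controls 2 and 4 (0.0652), and fatty acid synthesis with depth in the model (0.129). With depth in the model and the preset correlation, cholesterol synthesis passed (median 0.26, adjusted p = 0.0011 by camera). So did the stress response (median 0.26, adjusted p = 1.5e-04). Over its alternatives with 1 library left out, the adjusted p of cholesterol synthesis ran from 0.0088 to 0.327, of fatty acid synthesis from 0.0071 to 0.144, of the stress response from 3.1e-04 to 0.358 and of ribosomal proteins from 9.5e-09 to 6.5e-04. Leaving out 1 library gave 0 to 1 genes higher (1 without control 2), 0 to 5 lower and 1 to 4 lists. The lower count was 5 without control 1, 4 without MSNBA 4, 1 without control 3, and 0 without control 4, 5 or 6 or MSNBA 1, 2, 3, 5 or 6; lists were 2 without control 1, 3, 5 or 6 and 1 without MSNBA 4 or 6.

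Signs turned for results that did not pass in the reported test. Cyp17a1 had log2 fold changes of 0.098 without the filter, 0.16 after thinning, 0.0030 with a surrogate variable, 0.042 without controls 2 and 4, and -0.12 to 0.029 with 1 library left out. Nr5a1 had 0.0070 without the filter. List medians that turned were 0.0037 for mitosis with library size alone, -0.032 for the tricarboxylic acid cycle and -0.14 for hypoxia with the stricter filter, and -0.035 for the pentose phosphate pathway with the block. With depth in the model they were -0.17 for the pentose phosphate pathway, -0.0077 for oxidative phosphorylation and -0.058 for DNA replication. Without controls 2 and 4 they were 0.056 for Leydig cell regulators, -0.042 for cholesterol storage and efflux, -0.018 for the pentose phosphate pathway and -0.12 for DNA replication. With 1 library left out, medians ran from -0.093 to 0.014 for Leydig cell regulators, -0.0043 to 0.18 for cholesterol storage and efflux, -0.083 to 0.12 for the pentose phosphate pathway, -0.035 to 0.12 for the tricarboxylic acid cycle, -0.0069 to 0.12 for the unfolded protein response, -0.051 to 0.10 for hypoxia, -0.11 to 0.10 for mitosis and -0.078 to 0.11 for DNA replication. Without the low-count filter the median log2 fold change of the genes of the reported test moved to 0.14, against -0.0082. The signs of Cyp17a1 and Nr5a1 that turned in that setting go with this shift of all genes. Depth limits genes such as Slc2a5 and Hsd17b3 to the statement that no difference was detectable.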

Other observations

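The correlations and the genes named here were chosen after the data were seen, and no explanation was tested for them. Adjustment over the 4 relations does not cover the genes they were chosen from, so these p-values overstate the evidence.

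Star followed Ddit3, a transcription factor gene of the stress response, across the 12 libraries, with Pearson r = 0.886 (permutation p = 1.9e-04, adjusted p = 3.8e-04 over 4 relations) and Spearman rho = 0.902 (permutation p = 1.6e-04). Without the 2 libraries farthest from the median of Ddit3, r was 0.816, and it was 0.934 within controls and 0.857 within MSNBA. Cyp11a1 ran the other way, with r = -0.62 (permutation p = 0.0303, adjusted p = 0.0303), rho = -0.797 (permutation p = 0.00279) and r = -0.715 without those libraries, and it was -0.748 within controls and -0.717 within MSNBA. Hsd3b1 had r = 0.697 (permutation p = 0.0134, adjusted p = 0.0178) and rho = 0.615 (permutation p = 0.0373), with 0.443 without them, 0.958 within controls and 0.912 within MSNBA, so the relation over both groups pooled was weaker without those libraries. Asns had r = 0.868 (permutation p = 1.1e-04, adjusted p = 3.8e-04) and rho = 0.825 (permutation p = 0.00151), with 0.882 without them, 0.929 within controls and 0.727 within MSNBA. Ddit3 itself had a log2 fold change of 0.31 (SE 0.41) between groups, and its r with log2 depth was 0.0464.

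By edgeR, 17 of the tested genes, or 0.65%, had no overlap between groups, where chance gives 0.216%. Cebpa, a transcription factor gene, measured 607 ± 76.0 CPM in controls and 415 ± 45.4 CPM in MSNBA (SD, n = 6 per group), and the antioxidant enzyme gene Gpx1 measured 593 ± 82.3 and 415 ± 59.9 CPM. The splicing factor gene Prpf19 measured 444 ± 124 and 273 ± 32.4 CPM, the laminin gene Lamb2 424 ± 79.5 and 244 ± 62.1 CPM, and Nfic 517 ± 139 and 336 ± 20.7 CPM. Krtcap2, a subunit gene of the oligosaccharyltransferase complex, measured 293 ± 44.7 and 459 ± 64.4 CPM. Their adjusted p-values by edgeR were 0.101 for Cebpa, Prpf19, Lamb2 and Krtcap2, 0.104 for Nfic and 0.124 for Gpx1.

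Counts of Nrg1 rose with library total with a log-log slope of 0.55 (95% interval 0.27 to 0.83) and those of Actn4 with one of 0.72 (0.50 to 0.94), where the median of all tested genes was 1.03. The slopes were fitted without a treatment term. Both genes were picked as lower in MSNBA, the deeper group, which by itself pulls such slopes under 1. They are therefore no separate evidence of a depth effect. The first principal component held 24.5% of the variance and had r = -0.819 with log2 depth, and its scores did not separate the groups (exact two-sided permutation p = 0.232).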
